A study of Mus musculus with 60 samples.

How the data were processed

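Male C57BL/6N mice of 8 to 12 weeks were the source of the hepatocytes, which were plated on collagen and kept without serum for 24 h, per the labels. Cells then received 40 ng/ml HGF, 40 ng/ml IL-6, both or neither. RNA was labelled with biotin by the One-Cycle protocol and hybridised to Affymetrix whole-genome mouse arrays (Mouse430_2), per the labels' protocols. The deposited table holds log2 intensities of 45101 probe sets on 60 arrays. How the authors summarised and scaled the arrays is not given in the sources used here. Array medians lie between 4.88 and 4.97, so the values were taken as scaled between arrays and used as deposited. The series text speaks of biological triplicates, while the table holds 2 arrays per group and 4 at 0 h. None of the 1770 pairs of arrays held identical values. The number of arrays limits the precision.

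Probe sets were joined to genes by the array's probe table and reference gene names: 34958 carry 1 symbol, 932 carry several and 9211 are not listed with a gene. The last 2 kinds were left out. Each of 18194 genes was represented by its probe set with the highest mean over all arrays, and kept when this exceeded the 40th percentile of its array on at least 2 arrays, which left 14513 genes. Near-identical paralogues (Saa1 and Saa2, Hamp and Hamp2, the Orm and Akr1c families) share sequence, so that a value under 1 of these names can hold signal of its relatives. No genome build entered the work and no coordinates are given.

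Groups are the condition and hour in the labels. A linear model with 1 mean per group was fitted with limma 3.58.1 in R 4.3.3 (eBayes with a mean-variance trend, 31 residual degrees of freedom). Each comparison was a moderated F-test over 7 contrasts at matched hours, Benjamini-Hochberg adjusted over genes with a threshold of 0.05. The 8 comparisons were HGF, IL-6 and their combination against unstimulated cells, the combination against each single stimulus, IL-6 against HGF, the interaction, and unstimulated hours against 0 h. Rose and fell refer to the sign at the hour of the largest absolute difference. P-values at single hours, where given, were adjusted over genes within that hour. The interaction is the combination minus HGF, minus IL-6, plus unstimulated cells, all at the same hour.

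Gene lists (33 lists, 638 genes, of which 568 were measured and 47 have no probe set of their own name) were written from general knowledge. They cover immediate early genes, MAP kinase feedback and EGF-family ligands, STAT3 and gp130 genes, positive and negative acute phase proteins, complement and coagulation, G1/S, G2/M, ribosome biogenesis, CDK inhibitors and p53 targets. Further lists cover hepatocyte transcription factors, cytochrome P450 enzymes, conjugation and transport, bile acids, amino acids and urea, gluconeogenesis, glycolysis, fatty acid oxidation, lipogenesis, cholesterol synthesis, stress of the endoplasmic reticulum, NRF2, interferon, chemokines, survival and apoptosis, matrix, cytoskeleton, receptors, and markers of 5 other cell classes. They were tested with limma's camera at a preset correlation of 0.01 on averages over early (0.5 and 2 h), middle (4 and 8 h) and late (16, 24 and 32 h) windows, for the 3 stimuli and the interaction, 396 tests adjusted together. Camera tests of the contrasts between stimuli, and those at 8 h alone, were added later and adjusted each within their own set. Culture time was not tested with camera.

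Genes are named by rule: the 8 largest rises and falls that passed the F-test and whose 2 arrays lay beyond all reference arrays of that hour, the 4 members of each described list with the smallest adjusted p, and Cxcl10, Met, Il6ra, Il6st and Socs3. The groups, comparisons, tests, thresholds and settings to vary were fixed before the data were examined. The settings varied were quantile normalization, no filter and a filter at the 60th percentile, the mean over probe sets of a gene, a fit on the compared arms only, the replicate number as a block, a variance model without trend and with robust estimation, a 2-fold minimum, camera with an estimated correlation and on ranks, and leaving out each array in turn. Restrictions to ranges of hours that share a labelling class or hybridisation control range were chosen after the data were seen, as were the class step and the lists chosen for description.

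The replicate number was not used as a block in the principal fit: over 378 pairs of groups the residuals of same-numbered arrays correlated between -0.27 and 0.25, with a median of -4e-04. The pipeline was tested on simulated data with 50 genes changed at each size: HGF against unstimulated cells recovered 30 of them at 1.3-fold, 41 at 1.5-fold and 50 at 2-fold, and called 11 of 14290 unchanged genes. Of the list tests 2 of 2 changed ones and 0 of 394 others were called. The simulated genes varied independently, without labelling or hybridisation differences. The simulation therefore cannot show how often correlated genes give false list calls. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.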

Results

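The series followed primary mouse hepatocytes over 32 h after addition of hepatocyte growth factor (HGF), interleukin 6 (IL-6) or both, beside unstimulated cells of the same hours. It holds 60 arrays in 29 groups: 4 unstimulated arrays at 0 h, and 2 arrays for each of the 4 conditions at 7 later time points from 0.5 to 32 h. Values are log2 intensities, and 14513 genes passed the intensity filter. Differences are log2 differences at the hour where each gene moved most, with the standard error (SE) of the fit and an adjusted p for the F-test over all 7 hours. The series text calls the replicates biological, but the labels do not say whether the 2 arrays of a group came from separate animals. P-values measure the spread between these arrays, which may not include that between animals. The number of arrays limits the precision.

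The first principal component held 59.83% of the variance and followed time in culture, from a mean of -31.16 in unstimulated cells at 0 h to 48.95 at 32 h. IL-6 with HGF reached 64.89 at 32 h. Arrays of a group correlated at 0.996 to 0.999. Spiked labelling controls set some arrays apart: the dap transcript's 3' minus 5' signal had a median of 1.34 on the 10 unstimulated arrays of 0 to 4 h and 2.70 on 49 others. Every contrast of stimulated with unstimulated cells at 0.5 to 4 h therefore crosses 2 labelling classes, whereas 8 to 32 h and contrasts between stimuli do not, except that IL-6 24 h replicate 1 lay apart from both classes (3.99). For genes that peaked early, the text also gives the class step, the excess of the unstimulated change from 4 to 8 h over that of stimulated cells (median size 0.15, 95th percentile 0.50). A gene's own response between 4 and 8 h enters this step too. The hybridisation control bioB differed as well, at 8.46 to 8.72 on unstimulated arrays of 8 to 32 h. Stimulated arrays other than HGF at 0.5 h lay at 5.94 to 7.59. Every contrast with unstimulated cells over 8 to 32 h therefore crosses a bioB difference. Contrasts between stimuli can cross one too: IL-6 arrays of 0.5 to 8 h lay at 7.44 to 7.59 and HGF arrays of 2 to 24 h at 6.10 to 6.91. The hybridisation controls bioC and cre did not part in this way. On unstimulated arrays of 8 to 32 h bioC lay at 9.77 to 10.18 and cre at 13.60 to 13.71. Stimulated arrays overlapped them, with bioC at 9.77 to 10.30 and cre at 13.58 to 13.85.

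**Figure D1:**
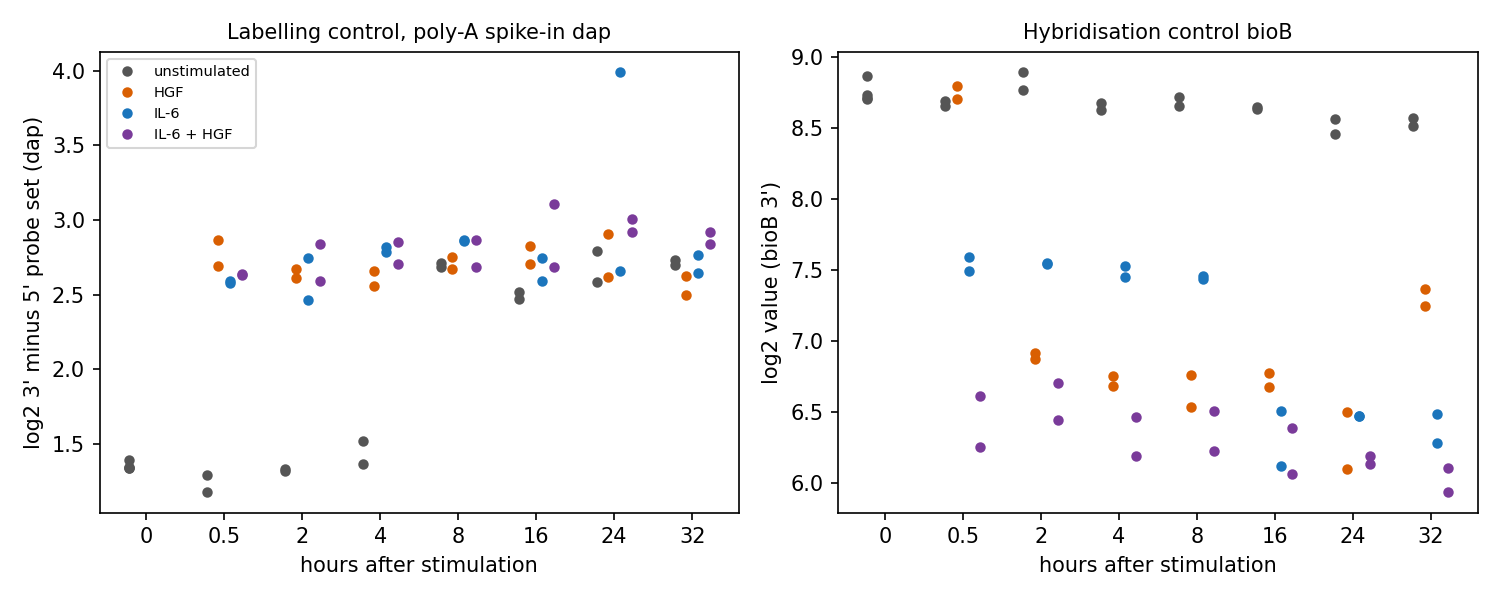
Left, 3' minus 5' signal (log2) of the dap labelling spike-in, and right, signal (log2) of the bioB hybridisation control, for each of the 60 arrays by hours after stimulation and condition. Unstimulated arrays of 0 to 4 h lie at 1.18 to 1.52 on the left, and unstimulated arrays lie at 8.46 to 8.89 on the right.

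HGF induced the zinc finger factor Egr2 within 0.5 h (3.16, SE 0.17, adjusted p = 9.31e-19, 2 arrays against 2; class step 0.31). Egr1 stood 2.26 higher at 2 h (SE 0.09, adjusted p = 3.76e-30; class step 0.96) and still 1.56 higher at 8 h. Later rises included the neutrophil chemoattractant Cxcl3 at 16 h (3.47, SE 0.25, adjusted p = 9.44e-22), the pluripotency and epithelial factor Klf4 at 16 h (2.35, SE 0.15) and the GTPase Rrad at 8 h (2.16, SE 0.13). The cornified envelope genes Ivl (2.56 at 4 h, SE 0.27; class step 0.20; 2.54 at 8 h) and Crct1 (2.58 at 32 h, SE 0.09) rose as well, as did Fam171b (2.60 at 24 h, SE 0.18).

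Acnat2, an acyltransferase, fell by 3.54 at 24 h under HGF (SE 0.18, adjusted p = 2.32e-24). The methyltransferase Bhmt fell by 3.36 at 24 h (SE 0.12), and Baat, which conjugates bile acids, fell by 3.29 at 16 h (SE 0.15). Rdh7 (-3.15, SE 0.12) and Akr1c20 (-3.14, SE 0.12) were lowest against unstimulated cells at 24 h, Akr1c19 (-3.14, SE 0.10) and the urea cycle enzyme Arg1 (-2.85, SE 0.20) at 16 h. The iron hormone Hamp fell by 2.84 at 16 h (SE 0.16, adjusted p = 5.3e-26). In all, 9082 genes differed from unstimulated cells: 4328 rose and 4754 fell, 156 and 363 of them at least 2-fold. Over 8 to 32 h alone 7991 genes passed.

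Immediate early genes carried the first wave. Of 18 measured, 15 rose, 1 fell and 2 did not pass (16 passed adjusted over the list alone), and over 8 to 32 h 12 rose and 4 fell. Their median difference was 0.52 at 0.5 and 2 h (camera adjusted p = 1.94e-13, and 0.000401 with an estimated correlation) and 0.41 at 8 h alone (adjusted p = 1.34e-10). Ier3 rose by 1.33 at 2 h (SE 0.05; class step 0.07), Maff by 0.83 at 4 h (SE 0.05; class step 0.18) and the AP-1 member Fosl1 by 1.64 at 8 h (SE 0.09). Among 16 MAP kinase feedback and EGF-family ligand genes 13 rose and 3 fell, all 16 also adjusted over the list alone. The phosphatases Dusp5 (1.99, SE 0.12; class step 0.06) and Dusp6 (1.92, SE 0.07; class step 0.54), the ligand Hbegf (1.84, SE 0.10; class step 0.41) and Phlda1 (1.20, SE 0.05; class step 0.12) were highest over unstimulated cells at 2 h. At 8 h they still stood 1.62, 0.79, 1.18 and 0.82 higher. This list's median was 0.49 at 4 and 8 h (adjusted p = 5.82e-10, and 0.00055 with an estimated correlation).

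Growth genes followed. All 23 ribosome biogenesis genes passed, 21 upward and 2 downward (23 adjusted over the list alone), and over 8 to 32 h all 23 rose. The pseudouridine synthase component Dkc1 (0.75, SE 0.04), Nolc1 (0.70, SE 0.06) and nucleolin, Ncl (0.50, SE 0.04) peaked at 16 h, and Nop58 at 4 h (0.71, SE 0.06; class step 0.49; 0.60 at 16 h). The late median was 0.35 (adjusted p = 7.46e-14, and 0.00549 with an estimated correlation). Of 34 G1/S and DNA replication genes 22 rose, 7 fell and 5 did not pass (29 adjusted over the list alone), and over 8 to 32 h 26 rose and 2 fell. Ccnd2 rose by 0.87 at 16 h (SE 0.12), the licensing factor Cdt1 by 0.50 at 16 h (SE 0.07), Slbp by 0.47 at 8 h (SE 0.06) and Cdc25a by 0.43 at 4 h (SE 0.07; class step 0.18; 0.33 at 8 h). Their late median was 0.23 (adjusted p = 1.74e-05, but adjusted p = 0.328 with an estimated correlation). Of 29 G2/M and mitosis genes 7 rose, 11 fell and 11 did not pass (18 adjusted over the list alone; late median -0.10, adjusted p = 0.227). Over 8 to 32 h, within a labelling class, 3 rose, 12 fell and 14 did not pass.

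Liver-specific programmes fell under HGF. All 14 hepatocyte transcription factors passed and fell (14 adjusted over the list alone), with a late median of -0.41 (adjusted p = 9.17e-06, and 0.0483 with an estimated correlation). Among them were the pregnane X receptor gene Nr1i2 (-1.45 at 8 h, SE 0.16), Onecut1 (-1.35 at 16 h, SE 0.17), Nr5a2 (-0.85 at 24 h, SE 0.08) and Nr1h3 (-0.88 at 2 h, SE 0.10; class step -0.61; -0.55 at 16 h). Of 20 conjugation enzymes and transporters 16 fell, 2 rose and 2 did not pass (18 adjusted over the list alone). Fmo5 (-2.53, SE 0.11) and Gstt1 (-0.86, SE 0.05) fell furthest at 24 h, Gstm3 (-2.34, SE 0.09) and Ugt2b5 (-1.51, SE 0.06) at 32 h. Of 24 complement and coagulation factors 19 fell, 2 rose and 3 did not pass (22 adjusted over the list alone). The protease Masp1 (-2.17, SE 0.09), C2 (-0.96, SE 0.06), Hc (-0.93, SE 0.06) and F9 (-0.75, SE 0.06) fell furthest at 24 h. Their late median was -0.45 (adjusted p = 1.94e-13, and 0.0417 with an estimated correlation).

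IL-6 raised Socs3, the feedback inhibitor of its own receptor complex, by 5.42 within 0.5 h (SE 0.09, adjusted p = 3.47e-51, 2 arrays against 2; class step 0.25) and held it 4.83 higher at 32 h. In unstimulated culture 28 of 30 positive acute phase proteins fell and 2 rose, so late differences from unstimulated cells hold this fall too. The fibrinogen chains Fga (4.60, SE 0.08, adjusted p = 8.29e-42) and Fgg (4.10, SE 0.06) were furthest above unstimulated cells at 32 h. At that hour Nat8f2 stood 4.14 (SE 0.15), Arrdc4 3.74 (SE 0.13), the BMP regulator Bmper 3.48 (SE 0.09) and Hamp 3.44 higher (SE 0.16). Cxcl5 rose by 3.37 at 24 h (SE 0.24).

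Arg1 (-2.88, SE 0.20), Akr1c20 (-2.85, SE 0.12), Akr1c19 (-2.80, SE 0.10) and the glucose transporter Slc2a2 (-2.42, SE 0.09) fell furthest at 16 h under IL-6. Adh1 (-2.45, SE 0.12) and the hormone Fgf21 (-2.40, SE 0.13) followed at 24 h, and Ddc (-2.57, SE 0.09) and the glutathione transferase Gstm3 (-2.56, SE 0.09) at 32 h. Under IL-6 7995 genes differed from unstimulated cells, 3399 up and 4596 down (183 and 194 at least 2-fold), and 6095 over 8 to 32 h alone.

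STAT3 target and gp130 signalling genes rose throughout: 14 of 17 rose, 2 fell and 1 did not pass (16 adjusted over the list alone). Their median went from 0.35 early (adjusted p = 5.3e-14) to 0.61 late (adjusted p = 6.13e-15, and 3.66e-05 with an estimated correlation). Cebpd, a transcription factor of the acute phase, rose by 2.97 at 8 h (SE 0.08), the oncostatin M receptor Osmr by 2.22 at 32 h (SE 0.08) and the kinase Pim3 by 1.18 at 2 h (SE 0.06; class step 0.13; 0.92 at 16 h). Of 30 positive acute phase proteins 26 rose and 4 fell (30 adjusted over the list alone), with a late median of 0.54 (adjusted p = 2.81e-27, and 0.000253 with an estimated correlation). Steap4 rose by 3.28 (SE 0.11) and Fgl1 by 3.05 (SE 0.07) at 32 h.

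Endoplasmic reticulum and integrated stress genes rose with them. HGF alone raised 14 of these 19 genes too and lowered 4, with 1 not passing (18 adjusted over the list alone). Averaged over 16 to 32 h, 11 stood higher under IL-6 than under HGF and 8 lower. Under IL-6 18 of 19 rose and 1 fell (19 adjusted over the list alone). At 8 h alone their median was 0.73 (adjusted p = 1.24e-39, and 1.08e-08 with an estimated correlation). The secreted chaperone cofactor Manf rose by 1.33 at 8 h (SE 0.06), the chaperone Hspa5 by 0.73 at 8 h (SE 0.04), the disulphide isomerase Pdia6 by 0.96 at 16 h (SE 0.07), and Xbp1 by 0.70 at 2 h (SE 0.05; class step 0.13; 0.52 at 8 h). Conjugation enzymes and transporters fell: 17 of 20, with 1 rise and 2 not passing (18 adjusted over the list alone) and a late median of -0.66 (adjusted p = 4.93e-13, and 2.77e-05 with an estimated correlation). Beside Gstm3 these were Fmo5 (-1.48 at 24 h, SE 0.11), Ugt2b5 (-0.90 at 32 h, SE 0.06) and Gstz1 (-0.89 at 16 h, SE 0.07). Of 21 fatty acid oxidation genes 18 fell, 2 rose and 1 did not pass (20 adjusted over the list alone; late median -0.22, adjusted p = 2.34e-06, and 0.0192 with an estimated correlation). The thiolase Acaa1b (-1.89 at 24 h, SE 0.10) and Cpt1a (-0.74 at 4 h, SE 0.07; class step -0.07; -0.69 at 8 h) fell, whereas Angptl4 rose by 1.23 at 24 h (SE 0.07).

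HGF and IL-6 moved the acute phase apart. Comparing IL-6 with HGF at 32 h, Hamp stood 5.43 higher (SE 0.16, adjusted p = 4.57e-38), Fga 5.30 (SE 0.08), Fgg 4.44 (SE 0.06) and Fgl1 3.31 (SE 0.07). Of 30 positive acute phase proteins 27 stood higher under IL-6 and 3 lower (30 adjusted over the list alone; late median 0.99, adjusted p = 2.18e-34, and 4.18e-05 with an estimated correlation). Against unstimulated cells HGF lowered 23 of these 30 and raised 6, with 1 not passing (29 adjusted over the list alone; late median -0.29, adjusted p = 1.54e-08, but adjusted p = 0.0501 with an estimated correlation). Ribosome biogenesis genes went the other way: 18 of 23 stood lower under IL-6 than under HGF, none higher, and 5 did not pass (20 adjusted over the list alone). Wdr12 (-0.68, SE 0.06), Dkc1 (-0.53, SE 0.04), Wdr43 (-0.48, SE 0.05) and Ncl (-0.40, SE 0.04) were lower at 24 h. In all 7426 genes differed, 3235 higher and 4191 lower under IL-6, with 286 and 124 at least 2-fold.

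**Figure D2:**
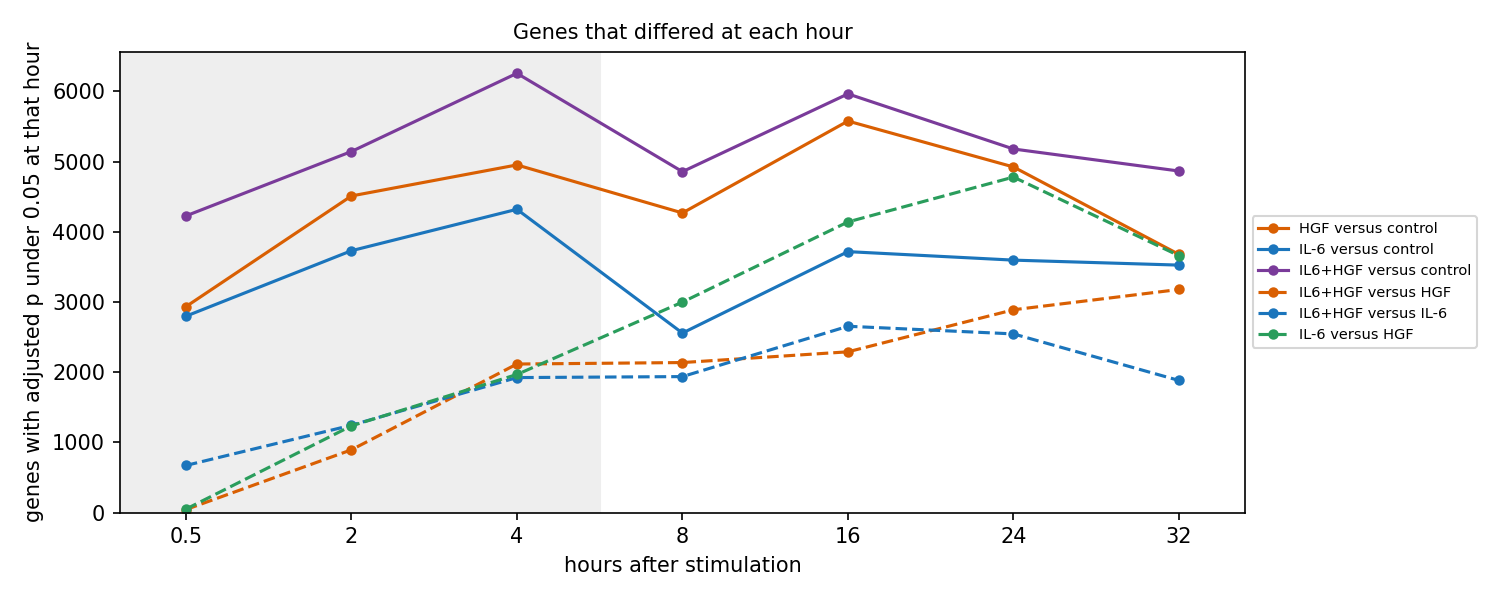
Number of genes with an adjusted p under 0.05 at each hour after stimulation, by comparison, with grey shading over 0.5 to 4 h, where stimulated and unstimulated arrays differ in labelling class. At 0.5 h HGF differed from unstimulated cells in 2933 genes and from IL-6 in 49.

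With both factors present, Socs3 rose by 5.56 at 0.5 h (SE 0.09, adjusted p = 1.91e-51; class step 0.25) and Egr2 by 3.94 (SE 0.17; class step 0.31). Cxcl10, a chemokine that binds the receptor Cxcr3, rose by 4.11 at 2 h (SE 0.15, adjusted p = 1.23e-27; class step 1.35). Late rises were in Cxcl5 (4.29, SE 0.24), Cxcl3 (4.28, SE 0.25), Fga (4.22, SE 0.08), Nat8f2 (4.12, SE 0.15) and Arrdc4 (3.86, SE 0.13), all at 32 h. Akr1c19 (-4.65, SE 0.10, adjusted p = 9.67e-41), Ddc (-4.21, SE 0.09), Akr1c14 (-3.63, SE 0.13) and Arg1 (-3.33, SE 0.20) fell furthest at 16 h, and Akr1c20 (-4.06, SE 0.12), Adh1 (-3.73, SE 0.12), Fgf21 (-3.54, SE 0.13) and Bhmt (-3.29, SE 0.12) at 24 h.

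Under the combination 9869 genes differed from unstimulated cells, 4548 up and 5321 down (324 and 513 at least 2-fold), and 8302 over 8 to 32 h alone. Immediate early genes rose in 16 of 18 cases, with 1 fall and 1 not passing (17 adjusted over the list alone; 13 rises and 4 falls over 8 to 32 h), and had an early median of 0.73 (adjusted p = 6.06e-17, and 6.92e-05 with an estimated correlation). Egr1 rose by 3.23 (SE 0.09; class step 0.96) and Ier3 by 1.68 (SE 0.05; class step 0.07) at 2 h, Zfp36, which destabilises cytokine transcripts, by 2.45 at 0.5 h (SE 0.08; class step -0.40), and Junb by 1.63 at 16 h (SE 0.07). STAT3 target and gp130 genes rose in 15 of 17 cases and fell in 2 (17 adjusted over the list alone; late median 0.78, adjusted p = 8.3e-10, and 0.000665 with an estimated correlation). Cebpd rose by 3.09 at 8 h (SE 0.08), Osmr by 2.27 at 32 h (SE 0.08) and Pim3 by 1.33 at 4 h (SE 0.06; class step 0.13; 1.08 at 16 h).

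Of 19 endoplasmic reticulum and integrated stress genes 18 rose and 1 fell under the combination (19 adjusted over the list alone), with a median of 0.93 at 8 h alone (adjusted p = 1.13e-29, and 1.55e-07 with an estimated correlation). Creld2 rose by 2.22 (SE 0.10), Manf by 1.51 (SE 0.06) and Hspa5 by 0.86 (SE 0.04) at 8 h. Herpud1 was lower at 2 h (-1.21, SE 0.07; class step -0.83) and 0.93 higher at 8 h. Conjugation enzymes and transporters fell in 18 of 20 cases, with 1 rise and 1 not passing (19 adjusted over the list alone; late median -0.92, adjusted p = 1.17e-14, and 1.34e-05 with an estimated correlation). Gstm3 fell by 3.04 at 32 h (SE 0.09), and Fmo5 (-2.72, SE 0.11), Ugt2b5 (-1.72, SE 0.06) and Gstt1 (-1.07, SE 0.05) were lowest against unstimulated cells at 24 h.

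**Figure D3:**
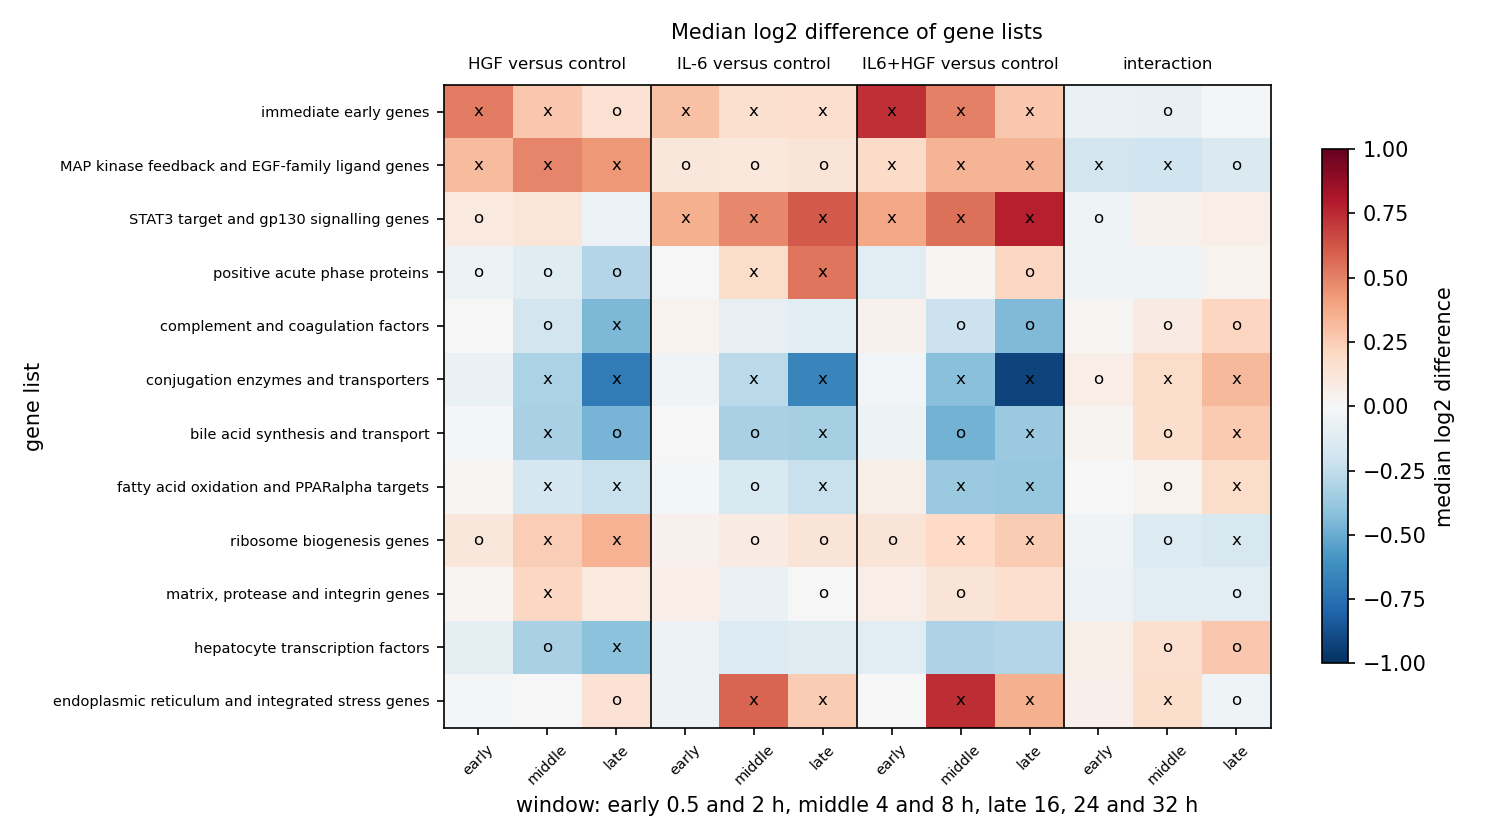
Median log2 difference of 12 gene lists in early (0.5 and 2 h), middle (4 and 8 h) and late (16 to 32 h) windows, for each stimulus against unstimulated cells and for the interaction, where o marks a camera call with the preset correlation only and x a call that also held with an estimated correlation. Only lists with at least 1 call under an estimated correlation are drawn, 12 of 33. Conjugation enzymes and transporters had late medians of -0.70 under HGF, -0.66 under IL-6 and -0.92 under the combination.

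Adding IL-6 to HGF raised the IL-6 target genes. Socs3 stood 5.17 higher at 0.5 h than with HGF alone (SE 0.09, adjusted p = 5.04e-50), and at 32 h Fga 4.92 (SE 0.08), Fgg 4.10 (SE 0.06), Steap4 3.62 (SE 0.11), Cebpd 3.14 (SE 0.08), Fgl1 2.94 (SE 0.07), Osmr 2.23 (SE 0.08) and Bcl3 1.33 higher (SE 0.06). Of 30 positive acute phase proteins 24 rose, 5 fell and 1 did not pass (29 adjusted over the list alone; late median 0.78, adjusted p = 1.35e-29, and 0.000129 with an estimated correlation). STAT3 target and gp130 genes rose in 14 of 17 cases, with 1 fall and 2 not passing (15 adjusted over the list alone; early median 0.26, adjusted p = 7.58e-39, and 4.1e-09 with an estimated correlation). All 19 endoplasmic reticulum and integrated stress genes rose (19 adjusted over the list alone), among them Creld2 (1.99, SE 0.10), Sdf2l1 (1.92, SE 0.09), Manf (1.45, SE 0.06) and Herpud1 (1.36, SE 0.07) at 8 h. This comparison called 6034 genes, 2571 up and 3463 down (197 and 69 at least 2-fold).

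Adding HGF to IL-6 raised immediate early genes further. Egr1 stood 1.79 higher at 4 h than with IL-6 alone (SE 0.09, adjusted p = 1.3e-23), Fosl1 1.28 at 4 h (SE 0.09), Fos 1.13 at 2 h (SE 0.11) and Ier2 0.68 at 2 h (SE 0.06). Fos was lower by 24 h (-1.06). Of 18 immediate early genes 16 rose, none fell and 2 did not pass (16 adjusted over the list alone; early median 0.38, adjusted p = 3.61e-31, and 3.19e-07 with an estimated correlation). Over 8 to 32 h 10 rose, 4 fell and 4 did not pass (late median 0.07, adjusted p = 0.021, but adjusted p = 0.297 with an estimated correlation). MAP kinase feedback and EGF-family ligand genes rose in 11 of 16 cases, with 2 falls and 3 not passing (13 adjusted over the list alone; median 0.32 at 4 and 8 h, adjusted p = 1.1e-10, and 0.000259 with an estimated correlation). Dusp6 rose by 1.15 (SE 0.07) and Phlda1 by 0.95 (SE 0.05) at 2 h, Hbegf by 1.12 (SE 0.10) and Dusp5 by 1.02 (SE 0.12) at 4 h. Complement and coagulation factors fell in 20 of 24 cases, with 3 rises and 1 not passing (23 adjusted over the list alone; late median -0.31, adjusted p = 5.53e-11, but adjusted p = 0.0819 with an estimated correlation). Masp1 (-1.16 at 24 h, SE 0.09), C9 (-0.87 at 32 h, SE 0.06) and Cfi (-0.50 at 32 h, SE 0.04) fell, and F11 rose by 0.93 at 16 h (SE 0.10). Positive acute phase proteins were lower: 23 of 30 fell, 3 rose and 4 did not pass (26 adjusted over the list alone; late median -0.28, adjusted p = 2.45e-16, and 0.00515 with an estimated correlation). The total was 6398 genes, 3362 up and 3036 down (55 and 105 at least 2-fold), though with quantile normalization 2970 were up and 3311 down.

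The interaction, the IL-6 difference with HGF present minus that without HGF, passed for 4872 genes (2749 positive and 2123 negative, 128 and 39 of at least 2-fold; 2532 and 2509 with quantile normalization) and for 2862 over 8 to 32 h alone. Arg1 had an interaction of 2.40 at 16 h (SE 0.29, adjusted p = 4.05e-08), Csad of 2.15 at 16 h (SE 0.14, adjusted p = 1.08e-19), Akr1c6 of 2.45 (SE 0.20), Dpys of 2.03 (SE 0.19), Rdh7 of 1.90 (SE 0.18) and Bhmt of 1.88 (SE 0.16) at 24 h, and the recombination gene Rad51b of 1.94 at 32 h (SE 0.21). Akr1c6 averaged 4.38 under the combination, in the dim range of the arrays. Each single stimulus lowered Arg1 at 16 h nearly as far as both together did. The dim end of the arrays may limit the combined fall of Arg1 and so enlarge its interaction, which was not tested. Ctse reached 1.87 at 0.5 h (SE 0.21), with a class step of -1.70 that enters the interaction with the opposite sign, and 0.96 at 24 h.

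Conjugation enzymes and transporters had positive interactions in 13 of 20 cases, with 2 negative and 5 not passing (15 adjusted over the list alone; late median 0.33, adjusted p = 4.74e-11, and 6.56e-05 with an estimated correlation). Gstm3 (1.87 at 32 h, SE 0.12), Fmo1 (1.86 at 24 h, SE 0.20), Fmo5 (1.51 at 16 h, SE 0.16) and Gstz1 (0.85 at 24 h, SE 0.10) had the smallest adjusted p. Complement and coagulation factors were positive in 18 of 24 cases, negative in 2, and 4 did not pass (21 adjusted over the list alone; late median 0.21, adjusted p = 2.5e-10, but adjusted p = 0.0822 with an estimated correlation). Serpind1 (1.03, SE 0.12), Masp1 (1.01, SE 0.12), Hc (0.63, SE 0.08) and Pros1 (0.56, SE 0.09) were largest at 24 h.

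Among negative interactions, Crct1 had -1.72 at 32 h (SE 0.13, adjusted p = 3.65e-16), the prostaglandin synthase Ptgs2 -2.06 at 16 h (SE 0.40), Ivl -2.05 at 24 h (SE 0.38) and adrenomedullin, Adm, -1.49 at 24 h (SE 0.17). HGF alone raised Ptgs2 by 2.09 and Adm by 1.26 at these hours, against 0.20 and -0.09 with IL-6 also present. At 2 h Cxcl3 had -1.62 (SE 0.35; class step -1.32; -1.37 at 8 h), Malat1 -1.61 (SE 0.21; class step 0.94; 0.30 at 24 h) and Cxcl5 -1.42 (SE 0.34; class step -0.96; 1.18 at 32 h). Egr2 had -1.44 at 0.5 h (SE 0.24; class step 0.31; 0.20 at 32 h). Of 23 ribosome biogenesis genes 17 were negative, 4 positive and 2 did not pass (22 adjusted over the list alone; 16 negative and 0 positive over 8 to 32 h; late median -0.16, adjusted p = 4.79e-12, and 0.0097 with an estimated correlation). Nolc1 (-0.52, SE 0.09), Nop58 (-0.48, SE 0.08), Dkc1 (-0.39, SE 0.06) and Ncl (-0.37, SE 0.05) were lowest at 16 h. MAP kinase feedback genes were negative in 7 of 16 cases, positive in 1, and 8 did not pass (8 adjusted over the list alone; median -0.22 at 8 h alone, adjusted p = 9.04e-06, and 0.00822 with an estimated correlation). Dusp6 had -0.92 at 24 h (SE 0.10), Dusp5 -1.05 at 2 h (SE 0.16; -0.80 at 8 h), Hbegf -0.90 at 2 h (SE 0.14; -0.53 at 24 h) and Phlda1 -0.40 at 32 h (SE 0.08).

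Cxcl10 stood above unstimulated cells of the same hour only for a time under each stimulus. Unstimulated means were 8.44 at 0 h (4 arrays) and 6.57 at 2 h. At 2 h Cxcl10 stood at 7.91 with HGF, 9.36 with IL-6 and 10.69 with both (2 arrays each). With HGF alone no later mean exceeded that of 0 h, so its difference at 2 h reflects a smaller fall than in unstimulated cells. At 4 h the HGF mean was 8.31, the IL-6 mean 6.85 and the combined mean 9.28. There the combination exceeded HGF by 0.97 (SE 0.15, adjusted p at that hour 3.54e-06) and IL-6 by 2.42 (SE 0.15), and the interaction was 1.21 (adjusted p at that hour 8.04e-05). The class step of 1.35 holds the decline of Cxcl10 in stimulated cells and enters the interaction with the opposite sign. At 2 h the interaction was -0.01, so the single log2 differences of 1.34 and 2.78 added up to the combined 4.11. By 32 h the combination lay below unstimulated cells (-1.57). The interaction reached 1.34 at 16 h (SE 0.21, adjusted p at that hour 1.22e-05), where the combination differed by -0.57, HGF by -1.01 and IL-6 by -0.90. In unstimulated cells Cxcl10 itself fell by 1.87 from 0 to 2 h (SE 0.13, adjusted p = 1.87e-16).

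**Figure D4:**
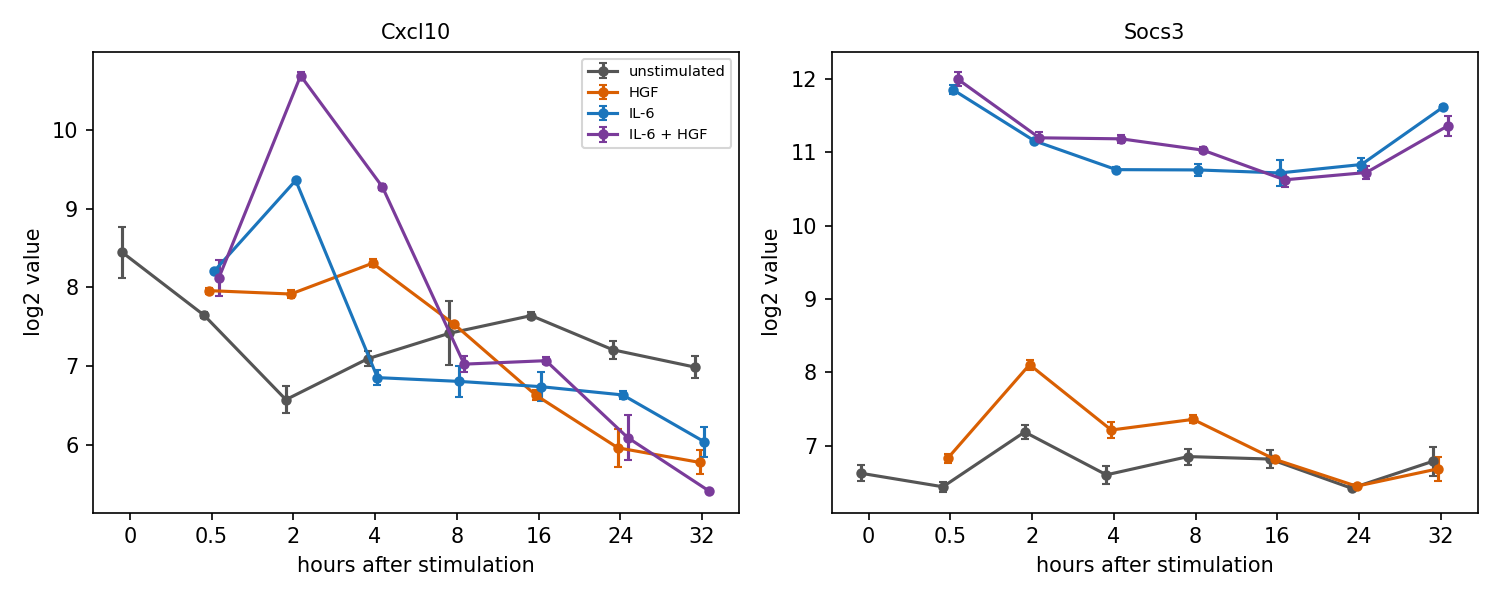
Group means of Cxcl10 (left) and Socs3 (right) in log2 intensity by hours after stimulation and condition, with bars for the SD (2 arrays per group, 4 at 0 h). Cxcl10 peaks at 10.69 at 2 h with IL-6 and HGF, and Socs3 reaches 12.00 at 0.5 h.

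Met, the HGF receptor, was 0.26 higher at 0.5 h with HGF (SE 0.05, adjusted p = 1.96e-07) and 0.24 higher with IL-6 (SE 0.05). Its class step of 0.29 is about as large. Within a labelling class the HGF difference was 0.07 at 8 h (adjusted p at that hour 0.364) and 0.14 at 16 h (0.0316). The IL-6 difference was -0.21 at 8 h (adjusted p at that hour 0.00223). With both factors Met fell by 0.31 at 8 h (SE 0.05, adjusted p = 1.47e-09). Its interaction was -0.28 at 16 h (SE 0.07, adjusted p = 4.45e-05). With the mean over probe sets neither this interaction (-0.19, adjusted p = 0.518) nor the HGF difference (0.11, adjusted p = 0.0633) passed. The IL-6 receptor Il6ra rose by 0.58 at 32 h with IL-6 (SE 0.08, adjusted p = 4.03e-09) and stood 0.61 higher with both than with HGF at 32 h (SE 0.08) and 0.65 higher with both than with IL-6 at 2 h (SE 0.08). Between IL-6 and HGF it differed by -0.62 at 2 h and 0.80 at 32 h, and in unstimulated cells it rose by 0.79 from 0 to 2 h. Il6st, the shared subunit, rose by 0.25 at 16 h with IL-6 (SE 0.05) and fell by 0.28 at 32 h with HGF (SE 0.05). Neither Il6ra (adjusted p = 0.0667) nor Il6st (adjusted p = 0.218) passed the interaction test, with largest values of 0.31 and 0.12 at 4 h. These 2 depend on the setting: with the mean over probe sets both passed (0.22, adjusted p = 0.00503, and 0.26, adjusted p = 0.0173), and Il6ra also passed with quantile normalization (0.30, adjusted p = 0.0204), among other settings. Socs3 rose by 0.92 at 2 h with HGF alone (SE 0.09, adjusted p = 1.02e-13), was 0.42 higher at 4 h with both than with IL-6 (SE 0.09), and had an interaction of -0.88 at 2 h (SE 0.13, adjusted p = 1.44e-05).

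In unstimulated cells 10878 genes differed from 0 h (4 arrays) over the 7 later hours, 5856 up and 5022 down (1160 and 719 at least 2-fold). By 32 h (2 arrays) Ms4a4d rose by 4.84 (SE 0.13, adjusted p = 2.94e-35), the growth factor homologue Fgf13 by 4.31 (SE 0.07), Slc25a36 by 4.22 (SE 0.17), Efemp1 by 4.20 (SE 0.19), the actin regulator Enah by 4.07 (SE 0.10), the stress factor Ddit3 by 4.03 (SE 0.12), caveolin, Cav1, by 3.94 (SE 0.14) and Marcks by 3.91 (SE 0.09). The deepest falls were in Arg1 (-5.81, SE 0.18), the fatty acid carrier Fabp1 (-5.59, SE 0.13), Crp (-5.22, SE 0.15), Baat (-5.04, SE 0.13), Sult1e1 (-4.85, SE 0.14), Slc26a1 (-4.82, SE 0.17), Defb1 (-4.77, SE 0.13) and Cyp2d26 (-4.62, SE 0.09). Arg1 and Defb1 thereby ended below the array median, so the dim end of the arrays may limit the size and rank of their falls. The 8 to 32 h arrays differ from 0 h in labelling class as well, and within a class 9528 genes differed between 16 to 32 h and 8 h.

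All 18 cytochrome P450 genes fell in culture (18 adjusted over the list alone): Cyp2e1 (-4.29, SE 0.06), Cyp3a11 (-3.83, SE 0.08), Cyp2c50 (-3.40, SE 0.06) and Cyp2d9 (-3.005, SE 0.06) at 32 h. Complement and coagulation factors fell in 20 of 24 cases and rose in 4 (24 adjusted over the list alone), among them C8g (-3.12, SE 0.06), Plg (-2.43, SE 0.07), C9 (-2.23, SE 0.05) and Serpinc1 (-1.89, SE 0.05). Cholesterol synthesis genes fell in 17 of 18 cases and rose in 1 (18 adjusted over the list alone): Dhcr7 (-2.55, SE 0.08), Idi1 (-2.47, SE 0.10), Fdps (-2.14, SE 0.08) and Msmo1 (-1.52, SE 0.06) were lower at 32 h. Of 17 CDK inhibitors and p53 targets 14 rose, 2 fell and 1 did not pass (16 adjusted over the list alone). Gadd45a rose by 2.82 (SE 0.08), Gadd45b by 2.08 (SE 0.06) and Trp53inp1 by 0.99 (SE 0.04) at 32 h, and Btg2 by 1.16 at 24 h (SE 0.05). Of 21 cytoskeleton genes 8 rose, 11 fell and 2 did not pass (19 adjusted over the list alone). Tuba1a rose by 2.21 at 24 h (SE 0.07), while Tubb6 (-1.83, SE 0.05), Tubb2a (-1.60, SE 0.05) and Tpm1 (-1.40, SE 0.04) fell furthest at 32 h. Of 29 mitosis genes 28 stood higher than at 0 h and 1 did not pass (28 adjusted over the list alone), across labelling classes. Within a class, 16 to 32 h against 8 h, 13 rose, 15 fell and 1 did not pass.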

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

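Tests chosen after the result was seen in this part are those of the hybridisation control, for the 0.5 h difference and the late interaction. Others are the reading of the dim end of the array in all metabolic lists and the 2 labelling tests of Cxcl10 at 4 h. Hepatocyte transcription factors were also read against HGF alone after the result was seen. The 8 hepatocyte lists were also picked from their results. The other tests had their bounds written first.

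Some genes answered HGF and IL-6 in opposite directions at the same hour. Between IL-6 and HGF the difference was 5.43 for Hamp at 32 h (HGF -1.99, IL-6 3.44), 3.98 for Fga at 24 h (-1.36 and 2.62), 3.45 for Steap4 at 24 h (-1.84 and 1.61), 2.91 for Crp at 24 h (-1.67 and 1.24) and 2.39 for the interferon-inducible GTPase Iigp1 at 32 h (-1.10 and 1.29). Fam171b went the other way, with -2.34 at 32 h (1.31 and -1.03). The interaction passed for 4872 genes. Cxcl10 changed direction with time: its HGF difference at 2 h exceeded that at 24 h by 2.58 (adjusted p = 1.98e-13), and the combined difference at 2 h exceeded that at 32 h by 5.69 (adjusted p = 1.21e-25).

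In the 0 h group, replicate 4 lay apart from the other 3 arrays in Arg1 (9.69), Defb1 (8.86) and the dap 3' minus 5' signal (1.39), 3 of 48 measures tested, where chance gives about 1 in 20. IL-6 24 h replicate 1 had a dap 3' minus 5' signal of 3.99, against medians of 1.34 on unstimulated arrays of 0 to 4 h and 2.70 on the rest, and a Gapdh 3' minus 5' signal of 0.75, against at most 0.25 on the other stimulated arrays. The hybridisation control bioB had a median of 8.66 on unstimulated arrays and 6.24 on IL-6 with HGF arrays.

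HGF differed from unstimulated cells in 2933 genes as early as 0.5 h, but from IL-6 in 49. A hybridisation difference marked by bioB cannot account for this, since HGF arrays of 0.5 h share the bioB level of the unstimulated arrays and still gave 2933 genes. An early response common to all stimuli is argued against: 93.0% of the 2688 genes with a shift of at least 0.2 moved the same way in unstimulated cells from 4 to 8 h, with no factor added. The labelling class would account for such a step, and the unstimulated 4 to 8 h change was a median 0.885 of the 0.5 h shift (0.004 in stimulated cells). The labelling class may therefore carry much of the breadth of the early difference, while time in culture enters the 4 to 8 h change as well.

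In 8 hepatocyte lists the late interaction was positive by camera at the preset correlation. With an estimated correlation some of these calls were lost, among them complement and coagulation factors and amino acid and urea genes. Where both single stimuli lowered a gene, this means a late fall smaller than the sum of the single falls. The 8 lists were 6 of metabolism beside complement and coagulation factors and hepatocyte transcription factors. Over their 139 members the late interaction had a median of 0.27 and was above 0 for 108, but over the 146 members of all 9 metabolic lists the median was 0.11, with 94 above 0. Of 14 hepatocyte transcription factors 12 stood higher late under the combination than under HGF and 2 lower, with IL-6 alone 6 higher and 8 lower. Over 8 to 32 h 10 rose, 1 fell and 3 did not pass against HGF. Neither the dim end of the array nor a saturating shared pathway would place a gene that both stimuli lower above HGF alone. A gene that IL-6 alone raised would stand there by addition. This list was also picked for its positive late interaction, which holds the same contrast. These values therefore do not decide for it. In the 8 lists the dim end of the array cannot be told apart from a joint action. In the 8 lists, 80 members above the 75th percentile at 24 h had a median interaction of 0.156 at 16 and 32 h, above the bound of 0.1 written before this value was seen. The test decides nothing, since these lists were picked for a positive late interaction. In the 9 metabolic lists 87 such members had 0.034, and the 59 dimmer ones 0.234, though 3 of these lists do not show the pattern. A hybridisation difference marked by bioB is argued against by a median of 0.053 between the combination and HGF at 0.5 h (0.037 to 0.080 over the 4 pairs of single arrays). There the HGF arrays have the bioB level of the unstimulated arrays and the combination arrays do not. A shared pathway that saturates stays open and was not tested.

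Cxcl10 at 4 h stood above both single stimuli. No single array of the 8 decides it, since the interaction of 1.21 stayed at 1.14 or more without any of them. The labelling class does not enter the contrasts between stimuli, and the combination exceeded the nearer single stimulus by 0.969. The class as the whole of the excess over the sum is argued against as well. Unstimulated Cxcl10 would then fall from 4 to 8 h by as much as the interaction, but its step, less the larger neighbouring step within a class, was -0.19, which leaves 1.014 of the interaction (SE 0.29). The interaction at 4 h also exceeded that at 2 h, across the same classes, by 1.22 (SE 0.34). A first bound, set at 0.5 of the interaction (-0.60), lay within 2 SE of that step, so a share of the excess from the class stays open. That Cxcl10 stood above each single stimulus and above their sum at 4 h may be biological, as a hypothesis found and tested on the same arrays.

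For each comparison 100 groupings of the arrays were compared, the real one included, with arrays exchanged within hours (for culture time among all unstimulated arrays), and only the real grouping (1 of 100) reached its count each time. The real count and the highest other were 9082 and 6213 genes for HGF, 7995 and 5701 for IL-6, 9869 and 7246 for the combination, 4872 and 2441 for the interaction, 6034 and 4000 for the combination against HGF, 6398 and 3691 against IL-6, 7426 and 5804 for IL-6 against HGF, and 10878 and 9160 for culture time. Camera calls numbered 137 and 118. In the same order the medians over the other groupings were 1189, 661, 1636, 0, 390, 346, 467 and 2521 genes and 72 camera calls. Random assignment of the arrays to groups is therefore an unlikely source of these counts. The regroupings cannot separate a stimulus from labelling or bioB differences that follow the groups.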

How the results depend on the processing

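Tests on restricted hours were chosen after the labelling classes were seen; the other alternatives were planned. Leaving out 1 array gave 8850 to 9097 genes for HGF (9082 with all), 7703 to 8024 for IL-6 (7995), 9617 to 9852 for the combination (9869), 4575 to 5058 for the interaction (4872), 5690 to 6108 for the combination against HGF (6034), 5941 to 6434 against IL-6 (6398), 7041 to 7534 for IL-6 against HGF (7426), 10349 to 10878 for culture time (10878) and 132 to 142 camera calls (137). The mean over probe sets gave 8185, 7104, 9052 and 4020 genes for HGF, IL-6, the combination and the interaction. A 2-fold minimum left 519 genes for HGF, 377 for IL-6, 837 for the combination, 167 for the interaction, 266 for the combination against HGF, 160 against IL-6, 410 for IL-6 against HGF and 1879 for culture time. Estimated correlation left 55 camera calls, ranks 127. The interaction held 2862 genes over 8 to 32 h and 3013 over 0.5 to 4 h, the latter across labelling classes. At 0.5 to 4 h the combination differed from HGF in 2423 genes and from IL-6 in 3339, and IL-6 from HGF in 2503. Within ranges of hours sharing a bioB level, the combination differed from HGF in 5250 (2 to 24 h) and from IL-6 in 4399 (16 to 32 h). Unstimulated cells at 0.5 to 4 h differed from 0 h in 2950. Quantile normalization moved the positive share of interaction genes from 56.4% to 50.2%, and the share that rose in the combination against IL-6 from 52.5% to 47.3%, so these balances of signs depend on scaling.

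Of 10227 values of 272 named results under the alternatives 10210 kept sign and call. With the mean over probe sets Met in culture time reversed to -0.19 (adjusted p = 0.0156), and 4 calls were lost: Met with HGF (0.11, adjusted p = 0.0633), the Met interaction (-0.19, adjusted p = 0.518), Il6st in the combination against IL-6 (-0.13, adjusted p = 0.074) and Cdh5 with HGF (-0.18, adjusted p = 0.309). The Il6ra interaction passed under 4 of the planned settings and without any 1 of 7 arrays, with an interaction of 0.31 or 0.38 and adjusted p from 0.0335 to 0.0473: unstimulated 2 h and 4 h replicate 1, HGF 8 h replicate 2, and IL-6 0.5 h replicates 1 and 2, 8 h replicate 2 and 16 h replicate 1. With every array it did not pass (adjusted p = 0.0667). The Il6st interaction passed with the mean over probe sets (0.26, adjusted p = 0.0173).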

Other observations

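The test of DNA replication against mitosis genes was chosen after the result was seen, as were the lists described here. Interferon-stimulated genes parted between the stimuli: 19 of 25 stood higher under IL-6 than under HGF, 3 lower and 3 did not pass (23 adjusted over the list alone; 16 higher and 5 lower over 8 to 32 h; late median 0.28, adjusted p = 3.31e-05, but adjusted p = 0.315 with an estimated correlation). Iigp1 was 2.50 higher at 24 h (SE 0.09, 2 arrays each), Irf1 1.05 at 32 h (SE 0.06), the peptide transporter Tap1 1.01 at 4 h (SE 0.09) and Psmb9 0.67 at 16 h (SE 0.09). Sinusoidal endothelial markers differed in the same contrast, with 9 of 13 higher under IL-6, none lower and 4 not passing (9 adjusted over the list alone; late median 0.30, adjusted p = 0.000397, and 0.0117 with an estimated correlation). Oxidative stress genes of NRF2 fell under the combination in 8 of 11 cases and rose in 3 (11 adjusted over the list alone; median -0.53 at 4 and 8 h, adjusted p = 0.000741, but adjusted p = 0.178 with an estimated correlation), while over 8 to 32 h, within a labelling class, they were near even with 6 falls and 5 rises. Against HGF, where no class is crossed, the combination lowered 9 of 11 and raised 2 (11 adjusted over the list alone). It lowered Cbr3 (-1.46, SE 0.15), Nqo1 (-0.96, SE 0.11), Srxn1 (-0.87, SE 0.07) and Gclm (-0.62, SE 0.04) at 24 h.

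Bile acid genes fell under the combination in 10 of 14 cases, none rose and 4 did not pass (10 adjusted over the list alone; late median -0.37, adjusted p = 9.12e-05, and 0.0289 with an estimated correlation). The phospholipid exporter Abcb4 (-2.28, SE 0.09) and Cyp27a1 (-0.99, SE 0.06) fell furthest at 24 h, the bile acid receptor gene Nr1h4 (-1.45, SE 0.10) and Cyp7b1 (-1.40, SE 0.07) at 16 h. Cytochrome P450 genes fell in 16 of 18 cases, with 1 rise and 1 not passing (18 adjusted over the list alone; late median -0.41, adjusted p = 6.12e-06, but adjusted p = 0.102 with an estimated correlation), among them Cyp2b10 (-2.55, SE 0.10), Cyp2d10 (-1.71, SE 0.08) and Cyp2d9 (-1.27, SE 0.07) at 32 h and Cyp3a11 (-1.96, SE 0.09) at 24 h. Amino acid and urea cycle genes had positive interactions in 13 of 16 cases and negative in 3 (16 adjusted over the list alone; late median 0.32, adjusted p = 6.37e-05, but adjusted p = 0.0795 with an estimated correlation), with Tdo2 at 1.77 (SE 0.20) and Asl at 0.56 (SE 0.09) at 16 h and Nags at 1.01 at 4 h (SE 0.11; class step -0.19). Of 12 glycolysis genes 6 rose, 5 fell and 1 did not pass under the combination (11 adjusted over the list alone), but over 8 to 32 h, within a labelling class, 9 rose, 1 fell and 2 did not pass (late median 0.31, adjusted p = 0.00255, but adjusted p = 0.234 with an estimated correlation). Slc2a1 rose by 1.22 at 4 h (SE 0.05; class step 0.32; 0.96 at 16 h), Pfkp by 0.63 at 16 h (SE 0.09) and Ldha by 0.59 at 32 h (SE 0.05), while Pkm was lower at 2 h (-1.12, SE 0.10; class step -1.43) and 1.10 higher at 32 h.

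Matrix, protease and integrin genes rose under HGF in 12 of 20 cases, 3 fell and 5 did not pass (15 adjusted over the list alone; median 0.20 at 4 and 8 h, adjusted p = 0.0011, and 0.0477 with an estimated correlation). Cd44 rose by 1.22 (SE 0.07) and Itga3 by 0.93 (SE 0.07) at 16 h and Ccn1 by 0.72 at 2 h (SE 0.05; class step 0.22), while Adamts1 fell by 1.03 at 8 h (SE 0.06). Gluconeogenesis and glycogen genes fell under HGF in 10 of 12 cases, with 1 rise and 1 not passing (11 adjusted over the list alone; late median -0.31, adjusted p = 0.0017, but adjusted p = 0.11 with an estimated correlation). Negative acute phase proteins fell under IL-6 in 10 of 11 cases and rose in 1 (11 adjusted over the list alone; late median -0.15, adjusted p = 0.0232, but adjusted p = 0.114 with an estimated correlation). Fatty acid and triglyceride synthesis genes fell under IL-6 in 9 of 15 cases, with 2 rises and 4 not passing (11 adjusted over the list alone). Chemokines and cytokines (8 up, 7 down, 5 not passing of 20), survival and apoptosis genes (6 up and 7 down of 13) and receptors and ligands (3 up, 4 down, 2 not passing of 9) were divided under the combination, with 15, 13 and 7 adjusted over the list alone. Over 8 to 32 h these had 6, 6 and 3 rises and 9, 4 and 3 falls.

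Markers of other liver cells were followed because plated hepatocytes can carry such cells. Of 13 sinusoidal endothelial markers 11 fell under HGF and 2 did not pass (11 adjusted over the list alone; late median -0.27, adjusted p = 0.0136, but adjusted p = 0.0749 with an estimated correlation), among them Emcn (-0.94, SE 0.18), Cdh5 (-0.67, SE 0.11), Fcgr2b (-0.65, SE 0.11) and Eng (-0.35, SE 0.08) at 32 h. With the mean over probe sets Cdh5 did not pass (-0.18, adjusted p = 0.309). Macrophage and Kupffer cell markers rose under IL-6 in 8 of 14 cases, with 2 falls and 4 not passing (10 adjusted over the list alone; late adjusted p = 0.362), but over 8 to 32 h, within a labelling class, 5 rose, 1 fell and 8 did not pass. Stellate cell and fibroblast markers (3 up, 3 down, 4 not passing of 10), cholangiocyte markers (3 up, 1 down, 2 not passing of 6) and lymphocyte, granulocyte and red cell markers (2 up, 1 down, 5 not passing of 8) went both ways under IL-6, with 6, 4 and 3 adjusted over the list alone. Over 8 to 32 h these had 2, 2 and 0 rises and 2, 1 and 0 falls.

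The differences under stimulation went in part with the later change of unstimulated cells. Across 14513 genes the difference from unstimulated cells at 16 h correlated with the unstimulated step from 24 to 32 h, by 0.408 for HGF, 0.314 for the combination and 0.204 for IL-6, with no arrays in common. Of 1627 genes with a later step of at least 0.5 in size, 77.4%, 72.3% and 65.9% had its sign. Stimulation that advances part of the change seen in culture would give such correlations. Faster loss of hepatocyte functions by another route would give the same sign. Not every list followed: of 30 positive acute phase proteins 28 fell and 2 rose in culture, but 26 rose and 4 fell under IL-6. The Actb 3' minus 5' signal moved too, from 0.48 and 0.51 on unstimulated arrays at 16 h to 0.71 and 0.72 at 32 h. On HGF arrays at 16 h it was 0.55 on both. A part of RNA quality was not tested.

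DNA replication genes stood above mitosis genes under HGF relative to unstimulated cells at 16 to 32 h, by 0.359 on average (exact permutation p = 0.0278 over 216 groupings within hours, 6 arrays per arm). G1/S means were 0.16, 0.24 and 0.28 at 16, 24 and 32 h, and G2/M means -0.37, -0.26 and 0.23. The G2/M fall at 16 h was not particular to HGF: the means were -0.33 with IL-6 and -0.43 with the combination, beside G1/S means of -0.09 and 0.03. S phase entry without mitosis before 32 h is only a candidate explanation, which a measure of DNA content would test.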
